A study of Mycolicibacterium smegmatis with 9 samples.

How the data were processed

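RNA sequencing libraries from 3 strains of *Mycolicibacterium smegmatis*, 3 libraries each, were compared. The strains carried the plasmid pMV261 with MSMEG_0179, pMV261 with MSMEG_0180, or pMV261 without either gene (the control, which the study text also calls wild type), and per the labels' protocols the cells were growing exponentially, RNA was harvested with Trizol and libraries followed standard Illumina protocols. Samples were grouped by strain, and each column of the deposited table was matched to a sample by its title. The authors deposited 1 table of FPKM values (reads scaled to gene length and to the total of the library) with 1 column per library. Reads were aligned with Bowtie2, per the submitters' processing notes; its version, the counting program, its strand setting and any filter are not given in the sources used here. Reads from overlapping genes, antisense pairs and near-identical copies may therefore have been split in a way that is not known.

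The table lists genes with positions on the chromosome. Of their locus tags, 6460 matched the RefSeq gene table given for the species (assembly ASM1500v1), and 99.7% of the matched genes shared a start or an end with it. Positions are those of the deposited table, counted from 1. Entries without a locus tag were at 0 in every library, and 141 genes were listed at 0 in all libraries. No genome sequence was used here, so GC content was not examined. All 9 value columns were used.

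In each library, FPKM multiplied by gene length was a whole multiple of 1 step for 99.98% to 100% of genes (within 0.02 of a whole number), which gave whole reads per gene and totals of 6308114 to 11424058. The recovered reads were used for checks and for an added alternative, and the tests reported were run on log2(FPKM + 1). Counting error is smaller in the MSMEG_0179 libraries 1 and 3 (11424058 and 10852504 reads) than in the others. A transfer-messenger RNA gene held between 10.33% and 15.35% of the reads, and ribosomal and transfer RNA at most 0.023%.

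Replicates were compared before any strain was tested. A chi-square test of the recovered reads over genes with at least 20 reads gave 1.12 to 1.36 per degree of freedom between replicates 1 and 2 of a strain, and 104 to 151 between either and replicate 3. Below 1000 reads per pair the values for replicates 1 and 2 were 0.989 to 1.09. Between 0.13% and 0.54% of genes differed between replicates 1 and 2, and 62.27% to 64.17% between either and replicate 3. Over all genes the chi-square test still found a difference between replicates 1 and 2 in each strain (p = 1.84e-72, 1.37e-11 and 2.55e-32), and below 1000 reads it still did in the control (p = 3.36e-05) but not in the others (p = 0.675 and 0.283), so they are not identical. Because they agree within sampling noise in nearly all genes while replicate 3 does not, the mean of replicates 1 and 2 was counted as 1 sample, which left 2 samples per strain and 6 in all. The design fixed before the data were examined had 9 libraries; its results are given as an alternative.

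The deviations of same-numbered libraries from their strain means correlated across genes between 0.682 and 0.881 in all 9 pairs, and 8 of the 9 libraries correlated best with a library of their own number. Library 2 of the MSMEG_0180 strain matched library 1 of the MSMEG_0179 strain (0.719) slightly better than library 2 (0.712). Replicates 1 and 2 share their distance from replicate 3, which alone makes their deviations correlate, so pairing of 1 with 1 and 2 with 2 is not shown. What the strains share is the split of replicate 3 from replicates 1 and 2. Values with the replicate number as a block are therefore given beside those without it. The block has 2 levels, replicates 1 and 2 together and replicate 3.

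Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested (6555 genes). Differences were tested with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes, two-sided), with all strains in 1 fit, and adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05. The residual degrees of freedom were 3 without the block and 2 with it. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. For 40 gene lists fixed before the data were examined, 36 had at least 4 members tested and were tested with camera (preset correlation 0.01), adjusted over the lists and the 3 comparisons together. Of the 108 list tests, 17 passed without the block and 18 with it, and 17 passed in both. With an estimated correlation 0 passed in either fit (camera in limma, where the preset correlation gave the 17 and 18). That version of camera tests with the residual degrees of freedom, 3 without the block and 2 with it, so hardly any list could pass. It therefore cannot tell whether correlation between genes accounts for the calls. The estimates themselves, made without the block from few samples, were 0.887 for the cytochrome bcc-aa3 oxidase and 0.456 for ATP synthase. They were 0.251 for Mce proteins, 0.213 for ribosomal proteins, 0.128 for the DosR regulon and 0.0964 for ESX-3. For these lists the p-values with the preset 0.01 may be much too small. The estimates for ESX-1 (-0.0159) and the WhiB family (-0.011) lay below the preset. With the rotation test fry, 0 of the 17 lists called without the block passed, and 10 of the 18 called with it. The lists for cytochrome bd oxidase, transfer RNA, ribosomal RNA and toxin-antitoxin genes had too few members tested. The lists that passed camera with the preset correlation are described with the comparisons, and the others did not pass it in any of them. With fry and the block 25 list tests passed, some of them not called by camera. The cholesterol catabolism list, for instance, had a fry adjusted p of 0.0297 in the MSMEG_0179 strain against control and in the direct comparison.

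Named genes followed a rule fixed before the data were examined. MSMEG_0178 to MSMEG_0181 were always named. For each comparison against control, the rule took the 10 largest increases and 10 largest decreases among genes past the threshold whose libraries did not overlap, whose mean in the higher group was at least the median of the genes tested (28.5 FPKM) and whose product is described, plus the 2 largest in each direction with any product; for the direct comparison it took 6 in each direction. It also took the 3 members with the smallest p of each list called. Because few genes passed without the block, the rule was also applied to the fit with the block, a choice made after seeing the data. Products are those of the deposited table. Symbols are also from it where it gives one (794 genes), and otherwise from the RefSeq gene table.

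The fitting code was tested on simulated data, in which 200 genes outside the 50 most abundant were changed in the MSMEG_0179 strain against control, with the real difference between replicate 3 and the others kept and 6430 genes tested. The spread between samples was set to a coefficient of variation of 12%, drawn for each gene independently. With the block, limma recovered 94% of genes changed 8-fold, 91.8% of those changed 4-fold, 66.7% of those changed 2-fold and 22% of those changed 1.5-fold, and 5.6% of its calls were false. These shares depend on the spread and the number of changed genes that were set, and need not hold for the real counts. Without the block it recovered 0% at each of these sizes, and in the direct comparison 28% of those changed 8-fold. In a first version, in which the most abundant genes could also be changed, 18.5% of the calls with the block were false (35 genes of 6442 tested), because changed abundant genes moved the library totals and with them the median of all genes, by 0.131 on the log2 scale; the abundant genes were then left unchanged. In the real data the median of all genes was 0.117 for MSMEG_0180 against control and 0.172 in the direct comparison, shifts of about that size, so the counts of these comparisons may hold false calls of this kind. Overlap and covariance between the comparisons were also computed in 100 simulated data sets with unchanged strains and shared controls. Pathway terms of the deposited table were tested with the hypergeometric test (one-sided, genes with a term as background), and tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.

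Alternatives fixed before the data were examined were median ratio scaling, quantile normalization, no filter beyond a nonzero value, a filter of at least 10 FPKM in 3 libraries, pseudocounts of 0.1 and 5, removal of the overexpressed, ribosomal and transfer RNA genes, fits of only the 2 strains compared, the replicate block, leaving out each library in turn, camera with an estimated correlation, fry, an adjusted p under 0.01 and a log2 fold change of at least 1. Wherever genes were removed, the FPKM of each library were then rescaled to the same sum, so these settings combine removal with a change of scale. The count models of the plan, meant for a deposited count table, were not run, and voom on the recovered reads was run instead. Added after seeing the data were the count of genes whose samples did not overlap with the strains swapped in replicate 3, thinning to equal depth, replicates 1 and 2 as separate libraries, voom on the recovered reads, removal of transfer-messenger RNA as well, and each alternative together with the block.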

Results

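Messenger RNA levels were measured by RNA sequencing in exponentially growing cultures of *Mycolicibacterium smegmatis* (formerly *Mycobacterium smegmatis*), a fast-growing, non-pathogenic relative of the tubercle bacillus. There were 3 strains with 3 libraries each. The first overexpressed MSMEG_0179, annotated as a regulator of the GntR family, from pMV261, a mycobacterial expression plasmid. The second overexpressed MSMEG_0180, annotated as an HTH-type transcriptional regulator, from the same plasmid, and the control carried pMV261 without either gene. The comparisons ask which transcripts differ when either regulator is overexpressed, and how the responses to the regulators differ. The deposited values are FPKM per gene, and whole reads recovered from them came to between 6308114 and 11424058 per library, with a median of 6819884. The floor for a gene of 1 kilobase, set at 3 reads in a library, lay between 0.263 and 0.476 FPKM, and covers counting error only.

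Each overexpressed gene stood far above its level in the other strains. MSMEG_0179 (chromosome positions 202876 to 203547, protein coding) had 12675, 12783 and 14299 FPKM in the 3 libraries of its own strain and 9.91, 13.7 and 12.8 FPKM in the control. MSMEG_0180 (positions 203664 to 204173, protein coding) had 15717, 15868 and 10382 FPKM in its own strain and 5.34, 4.04 and 8.72 FPKM in the control. On the log2(FPKM + 1) scale the difference was 9.99 for MSMEG_0179 (limma adjusted p = 0.000304) and 10.75 for MSMEG_0180 (limma adjusted p = 0.00789). MSMEG_0179 accounted for at most 0.961% of the reads of a library and MSMEG_0180 for at most 0.809%. The neighbour MSMEG_0178, an ATP-binding protein gene upstream of MSMEG_0179, rose in the MSMEG_0179 strain from 0.542 to 4.81 FPKM (log2 fold change 1.84 ± 0.305 SE, limma adjusted p = 0.00141 with the replicate block and 0.161 without it). Its control values, 0.39, 0.61 and 0.59 FPKM, lie near the floor of 3 reads. The gene ends at position 202866, beside the start of MSMEG_0179, and whether reads of the overexpressed gene were counted for it was not tested. MSMEG_0181, on the other side, had log2 fold changes of 0.06 in the MSMEG_0179 strain and -0.46 in the MSMEG_0180 strain and passed the test in neither.

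**Figure D1:**
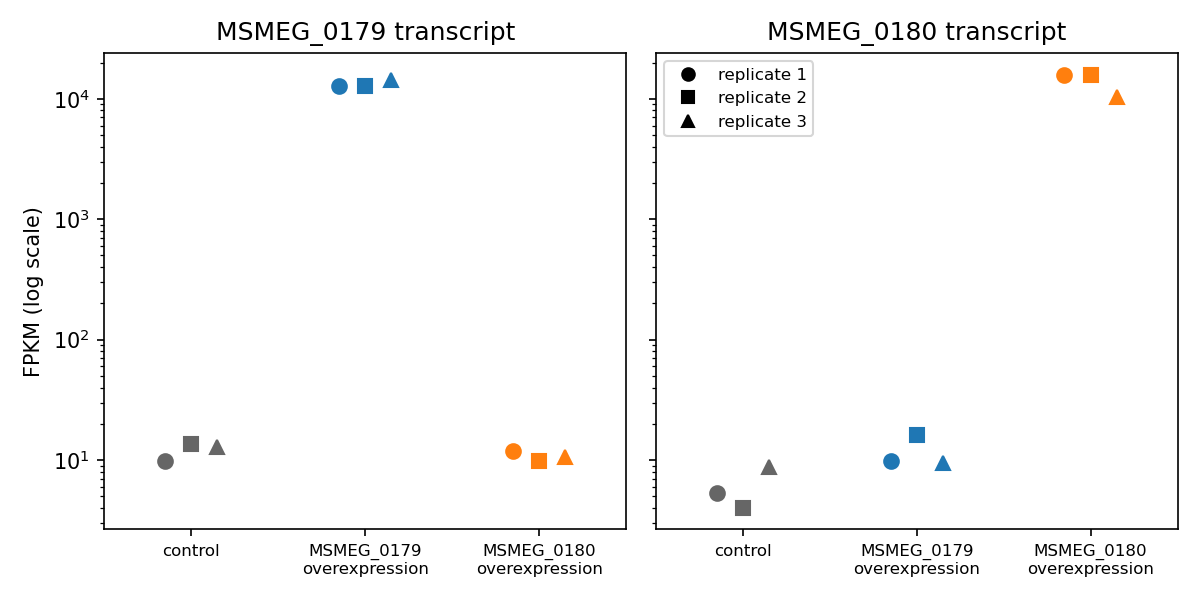
FPKM of MSMEG_0179 (left) and MSMEG_0180 (right) on a log scale in each of the 9 libraries, grouped by strain on the x axis, with 1 marker shape per replicate number. MSMEG_0179 lies between 12675 and 14299 FPKM in its own strain, and MSMEG_0180 between 10382 and 15868 FPKM in its own.

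Replicates 1 and 2 of each strain differed from one another by little more than sampling noise, whereas replicate 3 differed from both in 62.3% to 64.2% of genes, so replicates 1 and 2 were averaged and counted as 1 sample, giving n = 2 per strain. The distance of replicate 3 was shared by the 3 strains: of 55 ribosomal protein genes, for instance, 33 were lower and 11 higher in replicate 3 (median log2 difference -0.46, camera adjusted p = 0.00514, and adjusted p = 0.74 with an estimated correlation). Without a term for this split, limma called 16 genes, 1 gene and 20 genes in the 3 comparisons described below. With the replicate number as a block, which compares the strains within replicates 1 and 2 and within replicate 3, it called 1969, 1633 and 2287. The fold changes are identical in both fits. In what follows, a gene "rose" or "fell" when it passed an adjusted p of 0.05 with the block, and SE values come from that fit; this use of the block was settled after the small counts without it had been seen. Of the genes named below by the fixed rule, 10 of 34, 1 of 40 and 11 of 37 passed without the block in the 3 comparisons. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread among these samples, which may be technical.

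In the MSMEG_0179 strain, the largest increases after MSMEG_0179 itself included a choloylglycine hydrolase gene, several regulators and hypothetical genes, and the largest decreases an alcohol dehydrogenase gene, a forkhead-associated protein gene and an esterase gene. The choloylglycine hydrolase gene MSMEG_5454, of a family that cleaves amide bonds of bile salts, rose from 13.5 ± 1.71 to 370.2 ± 37.2 FPKM (SD, n = 2), a log2 fold change of 4.68 ± 0.139 (SE). The alcohol dehydrogenase gene MSMEG_1392 fell from 276 ± 12.1 to 9.02 ± 2.18 FPKM, 28.0-fold lower. The *mce* genes, which encode lipid importers of the cell envelope, and the genes of the ESX-1 type VII secretion system were higher as groups, and the siderophore genes lower. These group calls did not pass with an estimated correlation between genes (camera adjusted p = 0.867, 0.754 and 0.765), which hardly any list could with so few samples. The estimate for ESX-1, -0.0159, lay below the preset 0.01, so correlation between genes does not account for that loss. Those for the Mce proteins (0.251) and the siderophore genes (0.0264) lay above it, so a part for correlation stays open there. The rotation test fry gave adjusted p of 0.305, 0.0795 and 0.0795 without the block and 0.0319, 0.041 and 0.052 with it.

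Among the regulators, MSMEG_3177 rose by 3.90 on the log2 scale, the MerR family gene MSMEG_4765 by 3.07 and MSMEG_4370 by 2.85. The serine/threonine protein kinase gene MSMEG_5288 rose by 2.77, the short chain dehydrogenase gene MSMEG_4330 by 2.68 and the alpha/beta hydrolase gene MSMEG_2036 by 2.60. *cadA* (MSMEG_5403), a P-type ATPase annotated for cadmium transport, rose from 4.51 to 32.9 FPKM. MSMEG_4643, a resuscitation-promoting factor, a family of enzymes that cleave the cell wall of dormant cells, rose from 7.03 ± 0.771 to 48.0 ± 11.8 FPKM. Of genes without a known product, MSMEG_4751 rose most (log2 fold change 5.70 ± 0.365, adjusted p = 0.000908), but its adjusted p was 0.157 without replicate 3 of the MSMEG_0179 strain. The hypothetical gene MSMEG_5290 rose by 4.95.

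Decreases after MSMEG_1392 included the forkhead-associated protein gene MSMEG_1634 (log2 fold change -3.67), the esterase gene MSMEG_3437 (-3.31) and the *pks2* gene MSMEG_4727 (-3.08), which is annotated as mycocerosic acid synthase, an enzyme that builds methyl-branched fatty acids. MSMEG_0194, a serine esterase of the cutinase family and an abundant transcript, fell from 1905 ± 306 to 437 ± 123 FPKM. Alcohol dehydrogenase MSMEG_2079 fell from 926 ± 204 to 211 ± 12.5 FPKM. MSMEG_2116, the glucose-specific component of a sugar phosphotransferase system, fell by 2.07 on the log2 scale, the amidinotransferase gene MSMEG_1414 (*ddaH*) by 2.03, the dehydrogenase gene MSMEG_6557 by 2.33 and the amidohydrolase gene MSMEG_4063 by 1.86.

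Of 34 Mce proteins tested, 20 rose, 2 fell and 12 did not pass; adjusted over the list alone, 22 rose and 3 fell. MSMEG_1144 rose by 2.25 on the log2 scale and MSMEG_6540 by 1.63, while MSMEG_2850 fell by 0.99. The group median was 0.58 (camera adjusted p = 0.000276, and adjusted p = 0.867 with an estimated correlation). Of 26 ESX-1 genes, 12 rose, 2 fell and 12 did not pass, and the same counts held adjusted over the list alone. MSMEG_0066, the gene of the 6 kDa early secretory antigenic target, rose from 382 to 826 FPKM, and MSMEG_0065 beside it rose by 1.49 on the log2 scale and the PE family gene MSMEG_0063 by 1.01. The ESX-1 median was 0.48 (camera adjusted p = 0.00527, and adjusted p = 0.754 with an estimated correlation). Of 6 genes of the WhiB family, iron-sulfur proteins that bind DNA, 4 rose, 0 fell and 2 did not pass; adjusted over the list alone, 4 rose and 1 fell. They include MSMEG_0051 (log2 fold change 1.34), MSMEG_1831 (0.92) and MSMEG_1597 (0.66). The WhiB call (camera adjusted p = 0.0477) was lost with an estimated correlation (adjusted p = 0.867), after median ratio scaling (adjusted p = 0.067), quantile normalization (0.0625), no filter beyond a nonzero value (0.0519), a filter of at least 10 FPKM (0.0518), removal of the overexpressed, ribosomal, transfer and transfer-messenger RNA genes (0.0653) and with fry (0.168), and without control replicate 1 (adjusted p = 0.0577) or either of the MSMEG_0180 replicates 1 (0.0524) and 3 (0.0901). Of 23 genes of iron uptake through exochelin and mycobactin, the siderophores of this species, 8 fell, 0 rose and 15 did not pass; adjusted over the list alone, 9 fell. Among them the formyl transferase gene MSMEG_0014 fell by 1.17 and MSMEG_0016 by 1.49. MSMEG_0023, with the symbol *cwsA*, a cell wall gene that lies beside the siderophore genes, fell by 0.72. The median of the list was -0.44 (camera adjusted p = 0.000778, and adjusted p = 0.765 with an estimated correlation), and the call was lost with a filter of at least 10 FPKM (adjusted p = 0.0518).

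Over the 6555 genes tested, 890 rose and 1079 fell in the MSMEG_0179 strain with the block. The balance depended on scaling: with the block, median ratio scaling gave 991 higher and 995 lower, and quantile normalization 941 and 988. Removal of the overexpressed, ribosomal and transfer RNA genes, with every library then rescaled to the same sum of FPKM, gave 999 higher and 862 lower. Removal and rescaling were not run apart, so the turn cannot be credited to the removed genes. Without the block 10 were higher and 6 lower at the same threshold, and all 16 were also called with it. Without the block and without any of the 3 libraries numbered 3, the count was 1. The 16 included MSMEG_0179, MSMEG_1392, MSMEG_5454, MSMEG_3177, MSMEG_4765, MSMEG_4330, MSMEG_2036, MSMEG_5290, MSMEG_3437 and MSMEG_4727. The count with the block was 1094 without control replicate 3 and 1211 without replicate 3 of the MSMEG_0179 strain. The 2 samples of the strain and the 2 of the control did not overlap in 2447 genes, 37.3% of those tested, and in 375 genes, 5.7%, when strain and control were swapped in replicate 3. The swapped share is not a chance level. It counts genes with opposite effects in replicate 3 and in the other replicates, and 77.4% of genes had the same sign in both. A chance level for 2 samples against 2 was not computed.

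**Figure D2:**
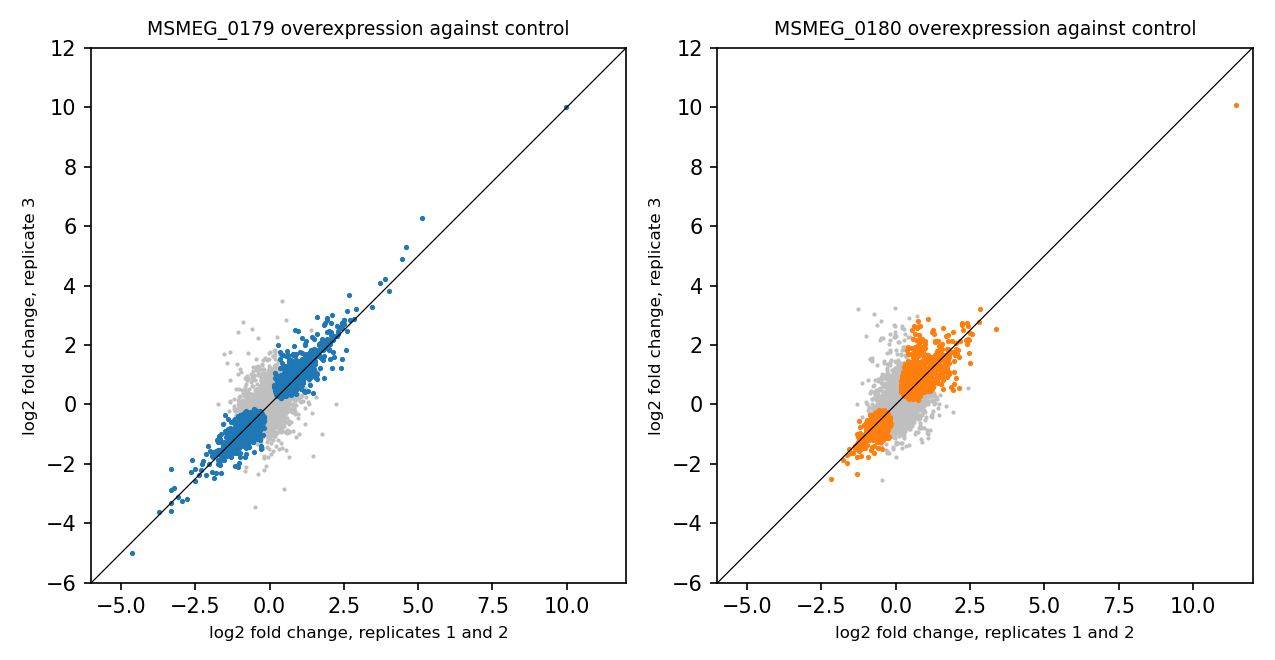
Log2 fold change against control of each of 6555 genes in replicates 1 and 2 (x axis) and in replicate 3 (y axis), for the MSMEG_0179 strain (left) and the MSMEG_0180 strain (right); coloured points passed an adjusted p of 0.05 with the replicate block, and the line marks equal values. Across genes the correlation of the axes was 0.788 on the left and 0.64 on the right, where genes are not independent replicates.

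In the MSMEG_0180 strain, the largest increases after MSMEG_0180 included a carbohydrate kinase gene, a D-amino acid deaminase gene and genes of a sugar transporter, and the decreases included genes of the ESX-3 secretion system and of the cytochrome bcc-aa3 respiratory oxidase. The carbohydrate kinase gene MSMEG_3785, of the PfkB family, rose from 4.01 ± 1.95 to 41.7 ± 24.0 FPKM (SD, n = 2), a log2 fold change of 3.02 ± 0.182 (SE). The ESX-3 gene *esxG* (MSMEG_0620) fell from 159 ± 24.6 to 54.6 ± 11.3 FPKM, and *qcrC* (MSMEG_4261), the cytochrome c subunit of the oxidase, from 766 ± 64.1 to 301 ± 67.3 FPKM. Ribosomal protein genes and the DosR regulon, a set of genes known to respond to low oxygen, were higher as groups. These calls did not pass with an estimated correlation between genes (camera adjusted p = 0.972 and 0.867), which hardly any list could with so few samples. With fry and the block, the ESX-3 (adjusted p = 0.0297), oxidase, DosR and ribosomal protein lists (0.0319 each) passed. The lists of iron uptake (fry adjusted p = 0.052), ATP synthase (0.0542) and acyl-CoA dehydrogenases (0.0669) did not. Without the block no list of this strain passed fry.

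MSMEG_3786, next to MSMEG_3785 and annotated as a D-amino acid deaminase, rose by 2.95 on the log2 scale. In a cluster of sugar ABC transporter genes, the substrate binding protein gene MSMEG_5574 rose by 2.57, and the permease genes MSMEG_5572 and MSMEG_5573 by 2.48 and 2.44, with the repressor gene MSMEG_5575 in the same cluster also higher. MSMEG_6176, the aldolase gene of galactonate breakdown, rose from 7.69 ± 0.535 to 41.0 ± 0.976 FPKM. The metallo-beta-lactamase gene MSMEG_5385 rose by 2.54 and the CAIB/BAIF family gene MSMEG_2023 by 2.38. These increases were not particular to the MSMEG_0180 strain. Each of these genes, and MSMEG_3785, was also higher in every MSMEG_0179 library than in any control library. MSMEG_2023, for instance, had 33.8, 35.1 and 34.9 FPKM in the MSMEG_0179 strain, 37.5, 37.7 and 44.3 in the MSMEG_0180 strain and 7.08, 6.91 and 7.06 in the control.

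Among the decreases, the hypothetical gene MSMEG_5664 fell most (log2 fold change -2.34 ± 0.107), from 535 ± 42.2 to 105 ± 9.40 FPKM. The oxidoreductase gene MSMEG_1742 fell from 2105 to 615 FPKM. MSMEG_6398, which encodes antigen 85-A, a mycolyltransferase of the cell envelope, fell from 2248 ± 359 to 834 ± 178 FPKM, and MSMEG_1350, a cyclopropane-fatty-acyl-phospholipid synthase gene, from 763 ± 142 to 292 ± 53.7 FPKM. The membrane protein genes MSMEG_3573 and MSMEG_1818 fell by 1.57 and 1.54 on the log2 scale, and the mechanosensitive channel gene MSMEG_1315 by 1.36.

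Of 12 ESX-3 genes, 10 fell, 0 rose and 2 did not pass, with the same counts adjusted over the list alone. ESX-3 is a type VII secretion system known to be needed for iron uptake through mycobactin. Its *eccE* gene MSMEG_0626 fell by 1.80, MSMEG_0621 by 1.68 and MSMEG_0622 by 1.32. The median of the list was -1.26 (camera adjusted p = 1.71e-12), and the call was lost with an estimated correlation (adjusted p = 0.589). Of 23 genes of iron uptake through exochelin and mycobactin, 11 fell, 0 rose and 12 did not pass, with the same counts adjusted over the list alone. The mycobactin gene *mbtG* (MSMEG_4509) fell by 1.39, MSMEG_4508 beside it by 1.36 and *cwsA* (MSMEG_0023) by 0.87. That median was -0.41 (camera adjusted p = 9.85e-07, and adjusted p = 0.589 with an estimated correlation).

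Of 6 genes of the cytochrome bcc-aa3 oxidase, 4 fell, 0 rose and 2 did not pass, also adjusted over the list alone. *qcrB* (MSMEG_4263) fell by 1.28, *ctaE* (MSMEG_4260) by 1.26 and *qcrA* (MSMEG_4262) by 1.22, and the genes of oxidase subunits 2 and I, MSMEG_4268 and MSMEG_4437, had log2 fold changes of 0.11 and 0.56 that did not pass. The camera adjusted p was 0.00789, against an adjusted p of 0.867 with an estimated correlation and of 0.0901 without replicate 3 of the MSMEG_0180 strain, where the median went from -1.24 to -0.70. Of 8 ATP synthase genes 5 fell and 3 did not pass; adjusted over the list alone, all 8 fell. *atpE* (MSMEG_4941) fell by 0.52, *atpC* (MSMEG_4935) by 0.61 and *atpD* (MSMEG_4936) by 0.57, and the last 2 of these had adjusted p of 0.0949 and 0.0537 without control replicate 3. The ATP synthase call (camera adjusted p = 0.00789, median -0.38) was lost with an estimated correlation (adjusted p = 0.867) and without replicate 3 of the MSMEG_0180 strain (adjusted p = 0.148, median -0.17).

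Of 55 ribosomal protein genes, 31 rose, 0 fell and 24 did not pass; adjusted over the list alone, 38 rose and 1 fell. *rpsJ* (MSMEG_1435) rose from 1018 to 1935 FPKM, *rplN* (MSMEG_1465) from 222 to 357 FPKM, and *rplJ* (MSMEG_1364) by 0.66 on the log2 scale, with an adjusted p of 0.0543 without control replicate 3. The ribosomal median was 0.34, 0.20 after median ratio scaling and 0.09 without control replicate 3. Its camera adjusted p of 0.0477 became 0.972 with an estimated correlation, 0.0589 after median ratio scaling, 0.0706 with no filter beyond a nonzero value, 0.0554 with a pseudocount of 5, 0.0624 with the overexpressed, ribosomal, transfer and transfer-messenger RNA genes removed, 0.0577 without control replicate 1 and 0.773 without control replicate 3, and was 1.89e-06 with the replicate block. Of 10 genes of the DosR regulon, 7 rose, 0 fell and 3 did not pass; adjusted over the list alone, 9 rose. Universal stress protein genes MSMEG_3940 and MSMEG_3945 rose by 0.92 and 0.78, and the GAF family gene MSMEG_5241 by 0.90. The DosR median was 0.67 (camera adjusted p = 0.0368), with an adjusted p of 0.867 with an estimated correlation, 0.0886 after median ratio scaling, 0.0777 with the overexpressed, ribosomal, transfer and transfer-messenger RNA genes removed and 0.231 without replicate 3 of the MSMEG_0180 strain. Of 81 acyl-CoA dehydrogenase genes, enzymes of fatty acid breakdown, 17 rose, 2 fell and 62 did not pass, also adjusted over the list alone. MSMEG_1497 rose by 1.54, MSMEG_2080 by 0.86 and MSMEG_2081 by 0.71. The median of that list was 0.30 (camera adjusted p = 0.0151, and adjusted p = 0.867 with an estimated correlation), and it was 0.09 after quantile normalization, where the call was lost (adjusted p = 0.207), as it was without replicate 3 of the MSMEG_0180 strain (adjusted p = 0.38).

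In all, 1037 genes rose and 596 fell in the MSMEG_0180 strain with the block, whereas MSMEG_0180 alone passed without it (605 genes had an unadjusted p under 0.05), and the count with the block was 626 without control replicate 3 and 1072 without replicate 3 of the MSMEG_0180 strain. The direction of many small changes depended on scaling: the median of all genes was 0.12 on the log2 scale as deposited and -0.01 after median ratio scaling, which turned the split into 664 higher and 998 lower, and quantile normalization gave 715 higher and 735 lower. None of the genes named by the fixed rule that passed, and none of the lists called, changed direction under median ratio scaling or quantile normalization. The 2 samples of the strain and the 2 of the control did not overlap in 2275 genes, 34.7% of those tested, and in 454 genes, 6.9%, when strain and control were swapped in replicate 3. As in the other strain, the swapped share is not a chance level, since 73.1% of genes had the same sign in replicate 3 and in the other replicates.

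**Figure D3:**
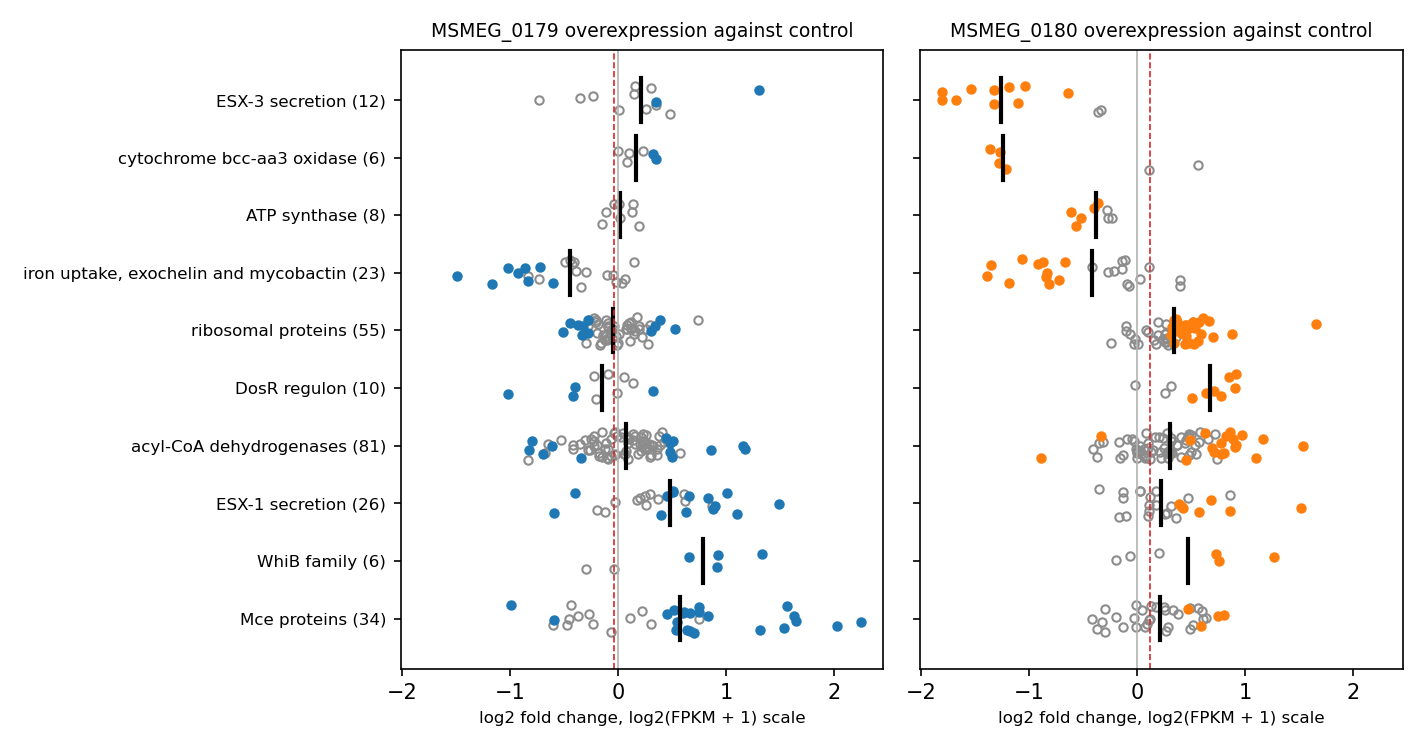
Log2 fold change against control of the members of 10 gene lists in the MSMEG_0179 strain (left) and the MSMEG_0180 strain (right), with the number of genes tested in brackets. Filled points passed an adjusted p of 0.05 with the replicate block, open points did not, black bars are list medians, and the dashed red line is the median of all genes; the ESX-3 median is -1.26 in the MSMEG_0180 strain.

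The direct comparison of the strains asks where the responses differ; its fold changes do not use the control, whose libraries enter its p-values through the common variance. The alcohol dehydrogenase gene MSMEG_1392 differed most after the overexpressed genes: it had 811 ± 105 FPKM (SD, n = 2) in the MSMEG_0180 strain and 9.02 ± 2.18 FPKM in the MSMEG_0179 strain, a log2 difference of 6.35 ± 0.115 (SE). MSMEG_2905, a transcriptional regulator gene, was higher in the MSMEG_0180 strain by 2.75, the DoxX family gene MSMEG_5179 by 2.64, the esterase gene MSMEG_3437 by 2.80, the forkhead-associated gene MSMEG_1634 by 2.68 and *mmsA* (MSMEG_2449), an enzyme gene of valine breakdown, by 2.48. Among the genes lower in the MSMEG_0180 strain were several that rose in the MSMEG_0179 strain: MSMEG_5454 (log2 difference -3.82), MSMEG_3177 (-3.29), MSMEG_4370 (-2.97), MSMEG_5288 (-2.76), MSMEG_4765 (-2.74), MSMEG_2036 (-2.71) and the hypothetical genes MSMEG_4751 (-4.48) and MSMEG_5290 (-3.89). Without replicate 3 of the MSMEG_0179 strain the MSMEG_4751 difference had an adjusted p of 0.175 and that of MSMEG_0180 itself 0.0805.

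ESX-3 genes were lower in the MSMEG_0180 than in the MSMEG_0179 strain in 11 of 12 cases (also adjusted over the list alone), with a median log2 difference of -1.62 (camera adjusted p = 1.27e-11, and adjusted p = 0.589 with an estimated correlation). Within the ESX-3 list *esxG* (MSMEG_0620) differed by -1.89 and MSMEG_0621 by -1.98. Among the 6 bcc-aa3 oxidase genes 4 were lower, also adjusted over the list alone, with *qcrA* (MSMEG_4262) at -1.57 and *qcrB* (MSMEG_4263) at -1.61 (camera adjusted p = 0.00681, and adjusted p = 0.867 with an estimated correlation). Of the 8 ATP synthase genes 6 were lower, and 7 adjusted over the list alone; *atpA* (MSMEG_4938) differed by -0.60 and *atpD* (MSMEG_4936) by -0.58. That call (camera adjusted p = 0.0119) was lost with an estimated correlation (adjusted p = 0.867), after quantile normalization (adjusted p = 0.0504) and without replicate 3 of the MSMEG_0180 strain (adjusted p = 0.147, median -0.18 against -0.46 with it). Of 34 Mce proteins, 14 were lower, 2 higher and 18 did not pass, and 15 were lower and 2 higher adjusted over the list alone; MSMEG_6540 differed by -0.82, MSMEG_1145 by -1.53 and MSMEG_2850 by 1.08 (camera adjusted p = 0.00088, and adjusted p = 0.867 with an estimated correlation). Of 26 ESX-1 genes, 10 were lower, 3 higher and 13 did not pass, and 11 were lower and 3 higher adjusted over the list alone; MSMEG_0065 differed by -1.11 and MSMEG_0066 by -0.99. The ESX-1 call (camera adjusted p = 0.0197) was lost with an estimated correlation (adjusted p = 0.765), after quantile normalization (adjusted p = 0.105), with a filter of at least 10 FPKM (adjusted p = 0.0516) and without replicate 3 of the MSMEG_0179 strain (adjusted p = 0.0582). DosR genes were higher in 7 of 10 cases, also adjusted over the list alone; MSMEG_3932 differed by 1.73, MSMEG_3940 by 1.33 and MSMEG_3944, annotated as a two-component regulator, by 1.25. The DosR difference (camera adjusted p = 0.0368) had an adjusted p of 0.867 with an estimated correlation, 0.0886 after median ratio scaling, 0.0777 with those RNA genes removed and 0.148 without replicate 3 of the MSMEG_0180 strain. Ribosomal protein genes were higher in 32 of 55 cases and in 33 adjusted over the list alone, among them *rpsJ* (MSMEG_1435) by 1.02 and *rplX* (MSMEG_1466) by 0.91. The camera adjusted p was 0.158, 3.83e-05 with the replicate block and 0.747 with the block and an estimated correlation. With fry and the block, ESX-3 (adjusted p = 0.0297), oxidase, DosR and ribosomal protein lists (0.0319 each) passed. Those of ATP synthase (fry adjusted p = 0.052), Mce proteins (0.0532) and ESX-1 (0.0758) did not.

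Over all genes, 1472 were higher and 815 lower in the MSMEG_0180 strain with the block, against 10 higher and 10 lower without it, and 930 higher and 1278 lower with the block after median ratio scaling, which moved the median of all genes from 0.17 to 0.01. Without replicate 3 of the MSMEG_0179 strain the count with the block was 1446. The count without the block was 1 without replicate 3 of either overexpressing strain, 3 without control replicate 3 and 3 in a fit of these 2 strains alone.

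The calls of the strains overlapped. Against the control, 333 genes rose in both strains and 252 fell in both, where independent lists of those sizes would share 140.8 and 98.1; 141 genes changed in opposite directions, where 251.6 would. Examples of increases in both strains were the galactonate genes MSMEG_6176 (log2 fold changes 2.21 and 2.27) and MSMEG_6177, *dgoD* (2.21 and 2.05), named after their values were seen, and an example of a decrease in both was *cwsA* (MSMEG_0023; -0.72 and -0.87). Both comparisons use the same control libraries, which can raise their overlap. Unchanged groups simulated against shared controls gave a mean of 0.75 genes called in the same direction, and at most 8. Without any changed gene hardly any call was possible, so this does not measure how far shared controls raise the overlap of lists of real calls. The covariance of the log2 fold changes across genes was 0.117, against 0.0209 in the simulation. The correlation was 0.373, against 0.498 in the simulation, and 63.2% of all genes had the same sign in both comparisons, against 66.7%. A shared control with unchanged strains gives the simulated correlation and share by construction. Real values below them therefore do not tell whether responses are shared. The controls were too few to be halved. The effect of MSMEG_0179 in replicates 1 and 2 and that of MSMEG_0180 in replicate 3 share no library. They had a covariance of 0.0853 and a correlation of 0.222 across genes, and the converse pairing 0.0942 and 0.272. Without the block the overlap was 0 genes in limma, since MSMEG_0180 alone passed in its strain; 743 and 605 genes had an unadjusted p under 0.05, and voom on the recovered reads likewise called 1 gene in the MSMEG_0180 strain. Without control replicate 3, the same-direction overlap with the block was 188 genes and the opposite-direction overlap 41.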

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

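Of the tests in this part, those of depth, of a shared batch, of the splits, of scaling, of abundant RNAs and of zinc uptake genes were chosen after the result was seen. The tests of gene length were written down beforehand. The test of the ferritin genes was written down after the exochelin and mycobactin values had been seen, so it is not treated as fixed in advance.

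The strains differed in direction for 141 genes, which passed the test with the replicate block in both comparisons against control with opposite signs. All 141 also passed in the direct comparison with the block. That contrast is the difference of the same effects in the same fit, so passing it follows from the opposite signs and is no further support. Of the 141 genes, 45 were higher in the MSMEG_0179 strain and lower in the MSMEG_0180 strain, and 96 the reverse. The largest difference was in the alcohol dehydrogenase gene MSMEG_1392, with log2 fold changes of -4.80 and 1.55 against control and a direct difference of 6.35 (adjusted p = 0.00366 without the block). It was followed by the hypothetical gene MSMEG_4141 (-1.75 and 1.32, direct difference 3.06), the regulator gene MSMEG_2905 (-1.48 and 1.27, 2.75) and the DoxX family gene MSMEG_5179 (-1.64 and 1.01, 2.64). Without the block the difference passed in 6 of the 141 genes, and did not in MSMEG_5179 (adjusted p = 0.0921). Without control replicate 3 there were 41 genes called in opposite directions.

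In every strain replicate 3 stood apart from replicates 1 and 2. With the strains fitted together 3676 genes differed, 1447 higher and 2229 lower in replicate 3, and ribosomal protein genes were lower as a group (33 of 55 passed and were lower, 11 were higher; camera adjusted p = 0.00514, and adjusted p = 0.74 with an estimated correlation), while universal stress protein genes were higher (9 of 14 passed and were higher, 2 were lower; camera adjusted p = 0.00806, and 0.74 with an estimated correlation). A difference in depth is argued against by thinning every library to 6308114 reads, after which at least 58.49% of genes still differed between replicate 3 and each of the others. Bins of gene length explained at most 14.4% of the variance of the log2 ratios, more than the 10% set beforehand as ruling length out and far under the 50% set as its mark, so a part for length remains open. The log2 ratios correlated at least 0.849 across genes between strains, so a batch of cultures or libraries shared by number is a candidate explanation, and whether cells or library preparation differed cannot be read from the labels; no biological explanation was tested.

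In the MSMEG_0180 strain more genes rose than fell (63.5% of calls with the block were higher). Removal of the overexpressed, ribosomal, transfer and transfer-messenger RNA genes left 62.5% higher, and 70.3% with transfer-messenger RNA kept. More genes thus still rose than fell without these RNAs. Each library was also rescaled to the same sum of FPKM, which can move the balance itself. Removal and rescaling were not run apart, so how far the removed RNAs contribute cannot be told. Other abundant messenger RNAs were not removed, so their part stays open. The lowest share in 3 classes of gene length was 61.2%, which argues against length as the cause. After median ratio scaling 40% were higher, but that scaling centres the gene ratios and thereby sets the balance itself, so the part of the normalization to total reads cannot be told apart and stays open. A true rise of many transcripts, as an effect of MSMEG_0180 overexpression, stays open and was not tested.

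The low ESX-3 transcripts of the MSMEG_0180 strain may reflect a known signal. ESX-3 is known to be repressed by iron in mycobacteria, and in the tubercle bacillus also by zinc, which need not hold in this species. Zinc-dependent repression is argued against, since the zinc uptake genes MSMEG_6045 to MSMEG_6047 had a median log2 fold change of 0.17. Iron-dependent repression stays open: 11 of 23 exochelin and mycobactin genes fell and 12 did not pass (adjusted p = 0.589 with an estimated correlation), and the ferritin genes MSMEG_3564 and MSMEG_6422, which iron is known to induce, had a median of -0.027, and the values of the exochelin and mycobactin genes had been seen before that test was written. Gene length is argued against by a median of -1.36 for the ESX-3 genes after subtraction of the median of their length bin. An effect of MSMEG_0180 overexpression on these genes stays open and was not tested.

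For each comparison the 6 libraries, taken singly and without the block, can be split in 10 ways into 3 against 3, too few for a share under 0.05. The real split gave 600 genes for MSMEG_0179 against control, 235 for MSMEG_0180 against control and 671 for the direct comparison, in each case the 1 split with so many, and the highest of the others gave 0. With replicates 1 and 2 merged and the block kept, the real pairs gave 2352, 1765 and 2277 genes, and swapping the strains in replicate 3 alone gave 0 in each. The swap moves any difference shared by the 2 sets of replicates into the error. The 0 thus follows from their agreement and is not a chance level.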

How the results depend on the processing

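The settings "separate libraries", "voom", "transfer-messenger RNA" and all those combined with the block were chosen after seeing the data. The largest dependence was on the replicate block, which raised the counts from 16, 1 and 20 genes (MSMEG_0179 against control, MSMEG_0180 against control, direct) to 1969, 1633 and 2287 and the overlap from 0 to 585 genes in the same and 141 in opposite directions; the block takes up the distance of replicate 3. The block also brought the ribosomal proteins past the threshold in the direct comparison (adjusted p = 3.83e-05) and lost no list called without it. With replicates 1 and 2 as separate libraries the counts without the block were 800, 500 and 984, with overlaps of 159 and 36; with the block MSMEG_0180 against control had 2597, and the overlaps were 1089 and 333, which counts near-identical libraries as independent.

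Without the block, fits of the 2 strains compared gave 1, 0 and 3 genes (fewer samples), and the MSMEG_0180 transcript itself had a log2 fold change of 10.75 with an adjusted p of 0.0583. An adjusted p under 0.01 left 1 gene for MSMEG_0179 and 3 in the direct comparison. Removing the overexpressed genes took away the 1 call for MSMEG_0180, with or without transfer-messenger RNA (0 genes each; limma, from 605 genes with an unadjusted p under 0.05 before removal), and left 12 in the direct comparison with transfer-messenger RNA removed too. The direct comparison had 42 genes at 10 FPKM and 38 with voom on recovered reads; the cause was not tested. With the block, an adjusted p under 0.01 gave 1140, 792 and 1361 genes and overlaps of 246 and 57, a log2 fold change of at least 1 gave 473, 359 and 621 and overlaps of 77 and 8, and voom gave an opposite overlap of 232.

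Leaving out 1 library gave 1 to 18, 0 to 1 and 1 to 22 genes without the block, the low counts coming without any replicate 3, and 1094 to 2325, 626 to 1716 and 1446 to 2253 with it. Where that left a strain with 1 sample, it was assumed to vary like the others. The overlaps ranged from 188 to 623 and from 41 to 139 with the block, and stayed at 0 to 0 without it. The log2 fold changes ranged from 9.89 to 10.10 for MSMEG_0179 and from 10.67 to 11.14 for MSMEG_0180, the latter with adjusted p of 0.0591, 0.112 and 0.0544 without replicate 3 of the MSMEG_0179, MSMEG_0180 and control strains. No named gene that passed and no called list changed direction; of those that did not pass, MSMEG_0181 in the MSMEG_0179 strain and MSMEG_0178 in the MSMEG_0180 strain did. Over the alternatives to the fit with the block, named genes stayed on their side of the threshold in 2365 cases, lost it in 98, of which 91 were the fit without the block, and gained it in 6. The planned count models, meant for a deposited count table, were not run, and voom on recovered reads stood in for them. Depth limits genes near the floor of 3 reads.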

Other observations

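The tests of neighbouring genes and of pathway terms in this part were chosen after seeing the data, and genes are named here after their values were seen. In the MSMEG_0179 strain a stretch of 9 neighbouring genes from MSMEG_4727 to MSMEG_4735 (positions 4819204 to 4836006) fell together, with a median log2 fold change of -2.55. It holds the mycocerosic acid synthase gene, an acyl-CoA synthetase gene (MSMEG_4731, -2.47) and a glycosyl transferase gene (MSMEG_4732, -1.64), and the next stretch, MSMEG_4737 to MSMEG_4741, which ends in an MmpL lipid transporter gene (MSMEG_4741, -1.13), fell with a median of -1.39. In the MSMEG_0180 strain MSMEG_4727 (-0.37), MSMEG_4731 (-0.03) and MSMEG_4741 (0.03) did not pass, and the 16 genes from MSMEG_4726 to MSMEG_4741 were higher there in the direct comparison, by a median of 2.05. The *mce* cluster from MSMEG_1141 to MSMEG_1150 rose in the MSMEG_0179 strain, with a median of 1.61 over 10 genes. MSMEG_6047, the binding protein gene of a cation ABC transporter, fell from 79.1 ± 18.1 to 25.6 ± 6.62 FPKM in that strain, with the metal regulator genes MSMEG_4486 (-1.08) and MSMEG_4487 (-0.93).

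Some stretches with sugar or polyol genes, picked after their values were seen, rose in both strains or in 1. The stretch from MSMEG_5571 to MSMEG_5577, a sugar ABC transporter with D-mannonate oxidoreductase and fructokinase genes, rose by a median of 1.81 in the MSMEG_0179 strain, and MSMEG_5570 to MSMEG_5577 by 2.29 in the MSMEG_0180 strain. The polyol cluster from MSMEG_3262 to MSMEG_3273 rose by medians of 1.39 and 1.19. A sorbitol and sugar transport cluster, MSMEG_3598 to MSMEG_3607, rose in the MSMEG_0180 strain by a median of 1.42 over 10 genes, and the arabinose genes *araB* (MSMEG_1713) and *araA* (MSMEG_1715) by 1.83 and 1.37. The DosR region, from MSMEG_3926 to MSMEG_3940, rose there as a stretch of 15 genes that includes subunits of a NiFe hydrogenase (MSMEG_3929, 1.17) and *ppsA* (MSMEG_3934, 1.25), and in the direct comparison the stretch of higher genes ran over 30 genes, from MSMEG_3926 to MSMEG_3955 (median 1.29). Stretches of at least 5 neighbours called in 1 direction held 299 genes in the MSMEG_0179 strain and 211 in the MSMEG_0180 strain, against at most 27 and 21 in 1000 shuffles of the calls over the genes. The shuffles ignore that neighbouring genes are transcribed together. Calls of any cause would cluster beyond them, so they do not bear on the cause of the stretches.

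Of 786 tests of pathway terms, 11 passed. In the MSMEG_0179 strain 66 of 204 genes with the term ABC transporters rose (30.4 expected, adjusted p = 1.07e-08), whereas of the 202 genes of the ABC transporter list fixed before the data were examined 39 rose, 23 fell and 140 did not pass, with a median of -0.02 (camera adjusted p = 0.513). In the MSMEG_0180 strain 9 of 13 genes of inositol phosphate metabolism rose (2.43 expected, adjusted p = 0.00785), and 6 of 9 genes of siderophore synthesis fell (0.784 expected, adjusted p = 0.00423). Neighbouring genes are transcribed together, so genes of a term are not independent and these p-values are too small.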
